A study of Mus musculus with 4 samples.

How the data were processed

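RNA from Hepa 1-6 cells was sequenced in 4 libraries: the input and the YTHDF1 precipitate of cells with a control guide and of cells with a guide for Usp5. Per the labels' protocols, cells were lysed, 10% of the lysate was kept as input, and the rest was incubated overnight with the antibody and protein G beads. RNA was extracted after washing, fragmented and depleted of ribosomal RNA. First-strand cDNA was made with random primers and template switching, and the libraries were amplified by PCR. No molecular identifiers are described, so reads from copies of 1 cDNA molecule are counted as often as they were sequenced.

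The authors deposited raw read counts per gene for all 4 libraries in 1 table. Per the submitters' processing notes, HISAT2 2.1.0 and featureCounts 1.6.3 were used with the mm10 mouse genome. The annotation release, the handling of strand, of reads with several matches and of duplicate reads are not given in the sources used here. Reads of overlapping or near-identical genes can therefore be shared or lost. The table lists 53465 Ensembl gene IDs, of which 31435 had 0 reads in all libraries. Each library's column was identified by the short name in its labels, and 0 columns of single samples were left over. The table does not pair IDs with gene names, and the reference table used here (49997 mouse genes, assembly GRCm38.p6) paired 0 of them. For this reason the 40 gene lists fixed before the data were examined, the levels of Usp5 and Ythdf1, and settings that need gene types, names or lengths were not analysed here.

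Counts were normalised with TMM factors over all 4 libraries (edgeR 4.0.16, R 4.3.3). The factors were 0.926 (control input), 0.969 (knockdown input), 1.05 (control RIP) and 1.06 (knockdown RIP). Genes with a mean of at least 1 CPM over the 4 libraries were compared. These were 12920 genes with 99.8% of all reads. Log2 ratios were taken after adding 0.5 counts, in proportion to library size. A gene was counted as higher or lower when its ratio was at least 2-fold and its 95% counting interval excluded 1. The interval was Clopper-Pearson's on the split of reads between 2 libraries, and for the ratio of enrichments it came from the sum of the reciprocal counts. A count of 0 allows up to 3 counts, which is between 0.0884 and 0.100 CPM in these libraries. These intervals cover counting error only. Wilson intervals of shares of genes and SEs of slopes take genes as independent, which they are not, and do not cover differences between libraries. Groups held 1 library each, so no test was made between knockdown and control and no p-value was computed across genes, which are not replicates. RIP over input has a value in each of the 2 lines, and after the data were seen a test over both was added: edgeR's quasi-likelihood test with fraction and cell line as terms, fitted to 4 libraries with 1 residual degree of freedom.

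The comparisons, the size rule and the rule for single genes were fixed before the data were examined. That rule took the 10 highest and 10 lowest genes per comparison by the bound of the interval nearest to no difference. It picked mostly genes with 0 reads in 1 library, which are described as a group. The 4 IDs printed were chosen after the values were seen, as the genes with the most reads, in each direction, among those past the size rule in inputs and RIP libraries with widened intervals.

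The scatter between 2 libraries was measured per gene as the squared deviation of the split of reads from its normalised expectation over the binomial variance. The median over genes at a mean log2 CPM between 0 and 6, scaled to the median of a chi-square variable, was 57.7 for the inputs and 18.4 for the RIP libraries. For the widened intervals, chosen after the data were seen, counts were divided by these values and 0.5 of the resulting units was added. For pairs of comparisons that share no library, the number of shared genes is given beside the product of the list sizes over the number of genes. That product does not take abundance into account. Lists of genes were set against 10000 random lists of the same size, matched on abundance in 20 bins. The lists used are the mouse cell cycle phase markers that scran 1.30.0 gives by Ensembl ID as pairs of a higher and a lower gene. An ID was kept for a phase when it was the higher gene in at least 10 pairs there. It also had to be the higher gene more often than the lower one in that phase and in no other phase. They were chosen after the data were seen.

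The code was tested on simulated data for knockdown against control input, with 12920 genes of which 200 were changed. With Poisson reads, 100 of 100 genes changed 4-fold and 100 of 100 changed 8-fold were recovered, and 4 of 12720 unchanged genes were counted. With reads in clumps of the measured size, 93 and 98 of 100 were recovered and 2773 of 12720 unchanged genes (21.8%) were counted. The widened intervals recovered 77 and 90 of 100 there and counted 189 unchanged genes (1.49%). The test over both lines was run on simulated clumped reads for RIP over input with 12920 genes, where it called 45 of 100 genes changed 4-fold, 70 of 100 changed 8-fold and 0 of 12720 unchanged genes. That simulation used 1 clump size per fraction at every abundance and no difference between the lines in RIP over input. The measured scatter was larger above a log2 CPM of 6, from 80.4 to 749 times the binomial variance in the inputs. The 0 false calls therefore do not give the error rate in the real data.

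Alternatives planned before the data were examined were library totals, DESeq2 1.42.0 size factors, upper-quartile factors, a mean CPM of at least 5, a minimum of 10 reads in all, 2 counts added, and 2-fold without an interval. Widened intervals, a mean log2 CPM of at least 5 and the test with the cell line as a block were added later. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.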

Results

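RNA bound by YTHDF1, a cytoplasmic protein that binds N6-methyladenosine in mRNA, was measured in Hepa 1-6 cells, a mouse hepatocellular carcinoma line, by RNA immunoprecipitation and sequencing (RIP-seq). The design set cells carrying a control guide against cells carrying a guide for Usp5, a ubiquitin-specific protease, which the labels call a knockdown. The cells with either guide are called 2 lines below, but both are Hepa 1-6 cells and not independent lines. From each, 1 library was made from the RNA recovered with an antibody to YTHDF1 and 1 from the lysate before precipitation (input). This gave 4 groups of 1 library each. The libraries held 30804293 counts (control input), 31751069 counts (knockdown input), 33941019 counts (control RIP) and 29898171 counts (knockdown RIP). At least 1 read was counted for 15909 and 15898 genes in the control and knockdown inputs and for 18333 and 17919 genes in the control and knockdown RIP libraries. The same gene had the most reads in all 4 libraries, with 2.48% (95% Wilson interval 2.48 to 2.49), 2.35% (2.34 to 2.36), 2.39% (2.39 to 2.40) and 2.48% (2.47 to 2.48) of counts in the order above.

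With 1 library per group, differences between knockdown and control have no replicate check, and no p-value is given for them or for RIP over input within a line. Genes are described by size: at least 2-fold, with a 95% counting interval that excludes no difference. The intervals cover counting error only, and reads amplified by PCR without molecular identifiers are not independent molecules. The genes are listed by Ensembl ID and were not paired with names here, so the level of Usp5, which would check the knockdown label, and that of Ythdf1 are not given. Abundance is the mean log2 CPM over the 4 libraries, and genes at 5 or more are called abundant below (5126 of the 12920 genes compared).

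The first comparison asked which RNAs the YTHDF1 antibody recovered from control cells. RIP over input was at least 2-fold higher for 2375 genes and at least 2-fold lower for 1944 genes of the 12920. Among the abundant genes, 453 were enriched in the RIP and 563 were depleted. Before the filter, over all 53465 IDs, 343 genes had at least 10 reads in each RIP library and 0 reads in each input. The reverse was seen for 30 genes. The inputs scattered more than the RIP libraries (57.7 and 18.4 times the binomial variance), which alone makes 0 reads in both inputs more frequent. These numbers are therefore not read as recovery with the antibody. The most read of the 10 most depleted genes over both lines made up 1.49% of counts in the control input and 0.0200% in the control RIP (457516 and 6783 reads), a log2 ratio of -6.40 (counting interval -6.43 to -6.36), or 84.3-fold lower. Of the 10 most enriched genes by the bound of the interval nearest to no difference, 9 had 0 reads in at least 1 library, and their mean levels were at most 3.96 CPM. Intervals widened by the excess of the scatter between libraries over counting error left 720 enriched and 1241 depleted genes. The input counts are widened more than the RIP counts, which by construction removes more of the genes with few input reads. No control precipitate was used here, so recovery with the antibody is not separated from recovery with the beads.

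In Usp5 knockdown cells, 2058 genes were enriched and 1771 genes were depleted in the RIP by the same rule. Among the abundant genes these numbers were 332 and 418. The same most read depleted gene had 567013 reads in the knockdown input and 7353 in the knockdown RIP, a log2 ratio of -6.31 (counting interval -6.34 to -6.28), or 79.4-fold lower, close to its value in control cells. With the widened intervals, 549 genes were enriched and 976 depleted.

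The enriched RNAs were then compared between the cell lines, whose ratios share no library. Enrichment in both lines was found for 883 genes, where independent lists of these sizes would share 378, and depletion in both for 816 genes, where independent lists would share 266. Opposite directions were found for 421 genes, below the 635 of independent lists. The numbers for independent lists do not take abundance into account. With the widened intervals the shared genes numbered 298 enriched (30.6 for independent lists) and 470 depleted (93.7), and 2 genes went in opposite directions (107). RIP was also tested against input over both lines with the line as a block (edgeR's quasi-likelihood test, 4 libraries, 1 residual degree of freedom), where any effect of the knockdown on enrichment counts as error. At a Benjamini-Hochberg adjusted p under 0.05, 1321 genes were enriched and 1461 depleted, of which 679 and 689 differed by at least 2-fold. Across all 12920 genes, which are not independent replicates, Pearson's r between the log2 enrichments of the lines was 0.228 and Spearman's rho 0.465. Among the abundant genes r was 0.847 and rho 0.844, and among the 7794 less abundant genes r was 0.167. By class of abundance, r went from 0.057 in the lowest class to 0.974 in the 81 genes at a log2 CPM of 10 or more.

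**Figure D1:**
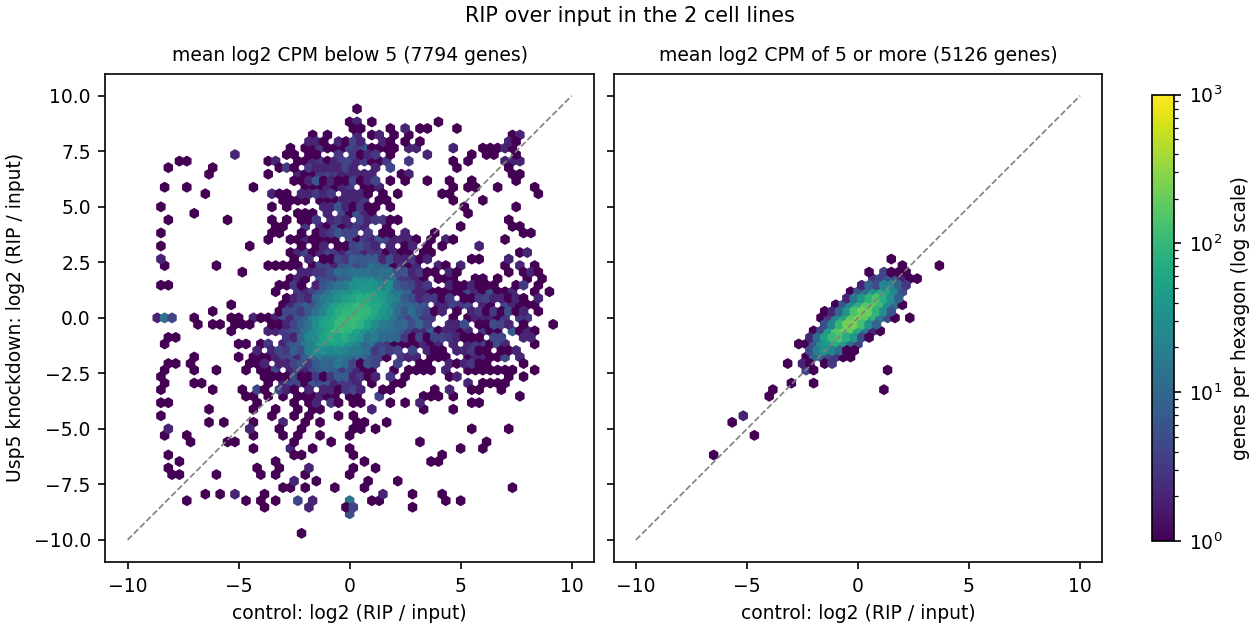
Log2 ratio of RIP over input per gene in control cells (horizontal) and Usp5 knockdown cells (vertical), for genes with a mean log2 CPM below 5 (left, 7794 genes) and of 5 or more (right, 5126 genes). Colour gives the number of genes per hexagon on a log scale and the dashed line marks equal ratios. Abundant genes lie along the line (r = 0.847), and less abundant genes spread along both axes (r = 0.167).

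Whether the RNA recovered with YTHDF1 differed after Usp5 knockdown was addressed by the ratio of the enrichments. It was at least 2-fold higher in knockdown cells for 1716 genes and lower for 1779 genes, and most of these were of low abundance: 75 abundant genes were higher and 59 were lower. In 126 of these 134 genes (94.0%) the ratio between the inputs was further from no difference than the ratio between the RIP libraries, with median sizes of 0.95 and 0.22 on the log2 scale. Over all abundant genes the log2 ratios also spread more between the inputs (SD 0.39) than between the RIP libraries (SD 0.24). Choosing genes by a large difference then favours those with large input ratios, so this share is not a separate result on Usp5. The abundant gene with the lowest ratio of enrichments had 382 reads in the control input and 6561 in the knockdown input, but 1122 and 778 in the control and knockdown RIP libraries, so that its enrichment was 20.4-fold lower in knockdown cells. The next gene had 5475 and 77968 reads in the inputs and 15722 and 16287 in the RIP libraries, and its enrichment was 11.3-fold lower. These genes were picked after their values were seen. With the widened intervals, 132 genes were higher and 114 lower over all genes (1.90% together). The widened rule was simulated for the inputs alone, where it counted 1.49% of unchanged genes, and not for the ratio of enrichments. These genes are therefore not read as differences beyond scatter.

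Genes were then chosen by the mean of their log2 enrichments over both lines, which does not require a 2-fold ratio in each line. Of the abundant genes, 356 had a mean enrichment of at least 2-fold, with a median log2 enrichment of 1.32 in control and 1.18 in knockdown cells. The median of the difference, knockdown minus control, was -0.14 (quartiles -0.44 and 0.14), and 63.2% of these genes were lower in knockdown cells. For the 437 abundant genes with a mean depletion of at least 2-fold the medians were -1.36 and -1.16 and the median difference was 0.20 (quartiles -0.06 and 0.46). The knockdown ratios thus lay nearer to no enrichment on either side.  When genes are chosen by the mean, a narrower spread in 1 line gives differences of these signs. They therefore restate the spread below and are not a separate result on the enriched RNAs. The SD of log2 enrichment over the abundant genes was 0.80 in control and 0.71 in knockdown cells. Over the same genes control enrichment had a slope of 0.95 (SE 0.00833) on knockdown enrichment, and the slope of knockdown on control enrichment was 0.76 (SE 0.00663). In the 1722 genes at a log2 CPM of 7 or more these slopes were 1.00 (SE 0.0105) and 0.84 (SE 0.00881). The SEs take genes as independent and do not cover differences between libraries.

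RNA abundance after Usp5 knockdown was compared between the inputs. Higher counts in knockdown cells were found for 1597 genes and lower counts for 1568 genes, and 39.4% of the less abundant genes but 1.91% of the abundant genes (98 genes) were among them. Among the abundant genes 52 were higher and 46 lower. For 552 genes 1 input had 0 reads, and in 421 of these the other input had at least 50 reads, up to 350. The scatter between the inputs was larger than counting error: in genes at a log2 CPM between 0 and 6 the squared deviation was 57.7 times the binomial variance. With the intervals widened accordingly, 101 genes were higher and 125 were lower. The 57.7 was measured on this same pair of inputs, so it includes any change with the knockdown, and the counts do not separate change from scatter. Simulated unchanged genes with clumps of this size passed the counting interval in 21.8% of cases and the widened one in 1.49%, beside 24.5% and 1.75% observed.

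**Figure D2:**
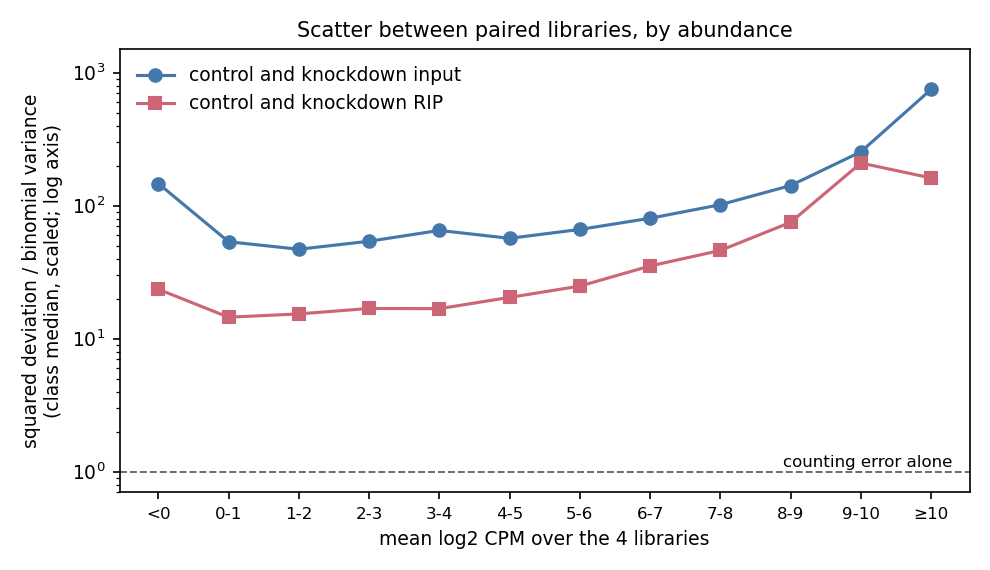
Squared deviation of the knockdown and control reads from an equal normalised share, divided by its binomial variance, as the median of each class of mean log2 CPM scaled to the median of a chi-square variable (log axis). Circles are the pair of inputs, squares the pair of RIP libraries, and the dashed line marks counting error alone. Between a log2 CPM of 0 and 6 the inputs lie between 47.0 and 66.3 and the RIP libraries between 14.5 and 24.9.

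The RIP libraries were also compared directly, without dividing by input. Knockdown counts were higher for 588 genes and lower for 599 genes, and of the abundant genes 2 were higher and 4 lower. The scatter between the RIP libraries was 18.4 times the binomial variance in the same range of abundance, below that of the inputs. With 0 reads in 1 RIP library there were 111 genes, of which 20 had at least 50 reads in the other. With the widened intervals, 77 genes were higher and 74 lower (1.17% of genes together). The share of unchanged genes that would pass was not simulated for this pair.

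**Figure D3:**
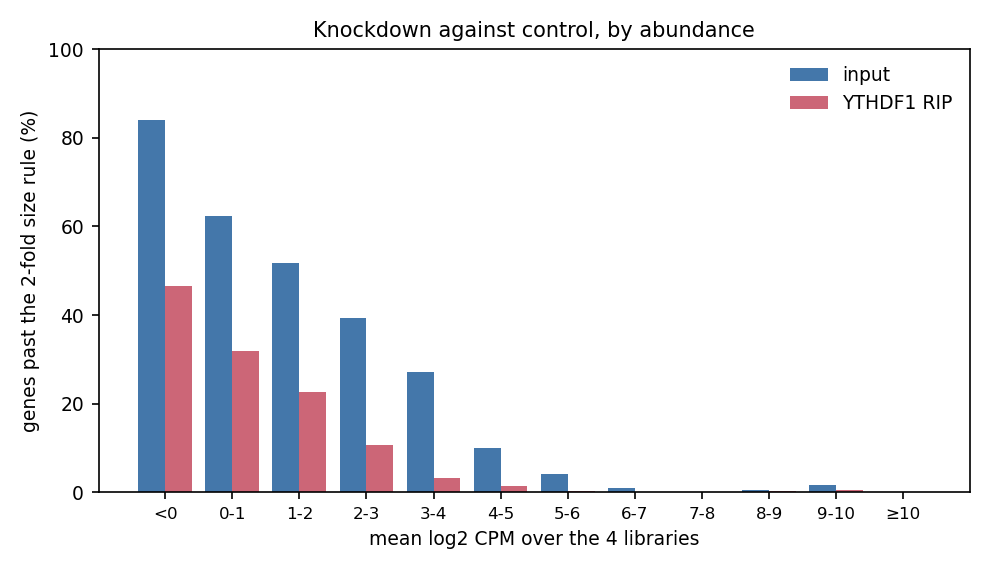
Percentage of genes at least 2-fold higher or lower in knockdown than in control cells, with a counting interval that excludes no difference, in classes of mean log2 CPM, for the inputs (blue) and the YTHDF1 RIP libraries (red). The share is lower in more abundant classes, from 84.0% to 4.09% of genes in the inputs and from 46.6% to 0.215% in the RIP libraries between the lowest class and the class from 5 to 6.

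The inputs and the RIP libraries came from separate libraries of the same cells, so genes that differed in both were counted. With counting intervals, 203 genes were higher and 217 lower in knockdown cells in both pairs (72.7 and 72.7 for independent lists), and 305 had opposite directions (145). The numbers for independent lists do not take abundance into account. Less abundant genes made up 3067 of the 3165 genes counted in the inputs and 1181 of the 1187 in the RIP libraries. That alone raises the number shared in either direction, so the excess is not read as agreement between the pairs. With the widened intervals, 4 genes were higher and 9 lower in both pairs, where independent lists would share 0.602 and 0.716, and 1 gene went in opposite directions (1.32). The genes with the most reads in each direction are given by ID; they were chosen after their values were seen. ENSMUSG00000031503 had 769 and 2283 reads in the control and knockdown inputs, a log2 ratio of 1.46 (widened interval 0.54 to 2.31), and 1813 and 3267 reads in the RIP libraries, a log2 ratio of 1.02 (0.66 to 1.37). ENSMUSG00000021950 had 390 and 1770 reads in the control and knockdown inputs and 375 and 935 in the RIP libraries, with log2 ratios of 2.07 (0.83 to 3.16) and 1.49 (0.73 to 2.20). ENSMUSG00000054932, among the more abundant genes, had 38097 and 17324 reads in the inputs and 27499 and 7814 in the RIP libraries, with log2 ratios of -1.25 (-1.44 to -1.05) and -1.64 (-1.80 to -1.49). ENSMUSG00000029368 had 24122 and 12704 reads in the inputs and 16975 and 5810 in the RIP libraries, with log2 ratios of -1.03 (-1.27 to -0.80) and -1.38 (-1.56 to -1.19). For both lower genes RIP over input was below 1 in each line, but reached 2-fold only in knockdown cells, with log2 enrichments of -0.79 and -1.19 in control and knockdown cells for the first and -0.83 and -1.17 for the second.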

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

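The widened intervals, the filter at a mean log2 CPM of 5 and the test with a block were chosen after the data were seen, the other settings before. DESeq2 size factors, upper-quartile factors, 2 counts added and 2-fold without an interval left every count within 1.5 times its value in the report. So did library totals, which moved the median log2 enrichment of all genes to 0.21 in control and 0.15 in knockdown cells and raised the enriched share of the genes counted from 55.0% to 66.4% and from 53.7% to 63.1%. No log2 ratio of a gene given by ID changed sign under any setting run, but with library totals the input ratios of ENSMUSG00000054932 and ENSMUSG00000029368 moved from -1.25 to -1.18 and from -1.03 to -0.97, the last under 2-fold. The counts depend on how far low counts are trusted, and the genes tested or the intervals differ by construction. In the order control RIP over input, knockdown RIP over input, ratio of enrichments, inputs, RIP libraries (higher, then lower), then shared enriched and shared depleted, widened intervals gave 720, 1241, 549, 976, 132, 114, 101, 125, 77, 74, 298 and 470. There the enriched share was 36.7% in control and 36% in knockdown cells, partly by construction, since input counts are widened more than RIP counts. A mean CPM of at least 5 (9923 genes) gave 1399, 1195, 1101, 993, 738, 789, 658, 630, 109, 115, 528 and 533, with Spearman's rho between the lines at 0.663. A mean log2 CPM of at least 5 (5126 genes) gave 453, 563, 332, 418, 75, 59, 52, 46, 2, 4, 212 and 280, with rho at 0.844, and depleted genes outnumbered enriched ones (enriched share 44.6% and 44.3%). With 10 reads in all (18511 genes) control and knockdown RIP over input gave 4408, 3070, 4179 and 2811, the inputs 2785 and 2832, the RIP libraries 2116 and 2063, the shared enriched genes numbered 1612 and rho was 0.306. The ratio of enrichments and the shared depleted genes stayed within 1.5 times there. The median differences in enrichment of the abundant enriched and depleted genes kept their sign under the other normalisations and with 2 counts added, the only settings that can move them. With the cell line as a replicate block, edgeR's quasi-likelihood test of RIP against input over both lines called 1321 genes enriched and 1461 depleted at an adjusted p under 0.05, with no minimum fold, beside 883 and 816 past the size rule in both lines. Knockdown against control has no such fit, since each line gave 1 lysate. Not run, because they need gene names, types or lengths, were TMM without mitochondrial and small non-coding genes, protein-coding genes alone, matching on gene length, and all settings for Usp5 and the fixed gene lists. Depth limits single genes: a count of 0 allows up to 3 counts, and clumps of reads widen this further.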

Other observations

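The phase markers and all tests below were chosen after the results were seen. Markers of the G1 phase of the cell cycle were under-represented in the YTHDF1 precipitate: the 99 measured of 103 had a median log2 enrichment of -0.41 in control cells, below all 10000 random lists matched on abundance (95% of them between -0.23 and 0.19), and of -0.29 in knockdown cells (percentile 0.265). The 84 G2/M markers had medians of -0.30 (percentile 1.03) and -0.16 (percentile 11.9), and the 68 S phase markers -0.09 (percentile 25.2) and -0.03 (percentile 44.1). With library totals, which shift all medians upwards, the values in control and knockdown cells were -0.23 and -0.16 for G1, -0.12 and -0.026 for G2/M and 0.09 and 0.10 for S phase, so the sign of the S phase values turned and G2/M in knockdown cells lay near 0. Over the markers at a mean log2 CPM of at least 5, the G2/M medians were -0.36 in control and -0.35 in knockdown cells, so the gap between the lines for G2/M was not seen there. Over these markers the G1 medians were -0.47 and -0.32 and the S phase medians -0.10 and -0.11. Between cell lines the median difference in enrichment, knockdown minus control, was 0.13 for G1 markers (percentile 98.3), 0.02 for G2/M markers (percentile 55.5) and -0.06 for S phase markers (percentile 17.9). The random lists were not matched on enrichment, and abundant genes with a mean depletion of at least 2-fold had a median difference of 0.20. The value for G1 markers, which were depleted, cannot be told apart from this general narrowing. In the inputs the medians of knockdown over control were -0.10 (percentile 6.50), -0.04 (percentile 37.0) and 0.01 (percentile 66.5) for G1, G2/M and S. The percentiles describe these libraries alone. The random lists were not matched on gene length. With no control precipitate, the values for the phase markers are not read as recovery with the antibody.

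The first pattern weighed was the scatter between the 2 inputs, 57.7 times the binomial variance. A change in RNA abundance with Usp5 knockdown should also shift the RIP libraries of the same lysates. Below a log2 CPM of 4, 2793 genes were past the size rule in the inputs and had at least 10 RIP reads. Only 52.5% of them shifted the same way there (Wilson interval 50.7 to 54.4, which takes genes as independent). This share argues against such a change as the cause for most of these genes, but it rests on 1 pair of inputs and 1 pair of RIP libraries. Among the 284 genes at 4 or more the share was 61.3% (55.5 to 66.7). It was 59.7% of 186 genes from 4 to 5, 57.9% of 76 genes from 5 to 6 and 86.4% (66.7 to 95.3) of the 22 at 6 or more. From 4 to 6 the shares also argue against such a change for most genes, with the same limit. A change in RNA stays open for the 22 genes and for part of the others. A candidate explanation for the bulk of the scatter is that few cDNA molecules were amplified into many reads: the excess then stays level with abundance, and its highest class median between a log2 CPM of 0 and 6 was 1.41 times the lowest, while the median reads per gene in the inputs went from 109 to 2710. In the class below 0 the excess was larger, at 147, as it was in the classes above 6, up to 749, and a level excess does not describe these classes.

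The second pattern was the wider spread of log2 enrichment in control than in knockdown cells, seen in 10 of the 12 classes of abundance. In the lowest classes, below a log2 CPM of 1, the order was reversed. Over all 12920 genes the SDs were 1.66 in control and 1.69 in knockdown cells. Weaker recovery of the enriched RNAs in the knockdown RIP library would make the ratio between the RIP libraries fall with mean enrichment. The slope of that ratio over the abundant genes was -0.020. Mean enrichment holds the same RIP libraries, so unequal scatter between them also shifts this slope, and it does not decide the question. The ratio between the inputs had a slope of 0.104. Mean enrichment holds the same inputs too, and more scatter in the control input alone gives a positive slope. A higher abundance of enriched RNAs in the knockdown input therefore cannot be told apart from scatter, nor an effect of Usp5 from a difference between 2 single libraries. Gene-level scatter in the control libraries, independent of the knockdown libraries, is a candidate. It leaves the slope of control on knockdown enrichment at 1, or below 1 where the knockdown libraries scatter too. A slope of 1.00 would then leave almost no scatter in the knockdown libraries. In the 2 lowest classes the SDs were 4.37 and 2.35 in control and 4.64 and 2.46 in knockdown cells. More scatter in the control libraries at every abundance would not give that order. The slope was 0.95 (SE 0.00833) over the abundant genes, 0.99 (SE 0.00888) at a log2 CPM of 6 or more and 1.00 (SE 0.0105) at 7 or more, but a real difference together with scatter in the knockdown libraries could give the same slopes.

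The abundant genes with the lowest ratios of enrichments, knockdown over control, had ratios between the inputs of 15.9-fold (382 and 6561 reads in control and knockdown) and 13.2-fold (5475 and 77968 reads). Their log2 ratios between the RIP libraries were -0.36 and 0.22.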
